A study of Mus musculus with 8 samples.

How the data were processed

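RNA was sequenced from mouse R1 embryonic stem cells (ESCs) and day 3 embryoid bodies (EBs) with and without a Zfp462 knockout, in 8 poly(A)-selected libraries, 2 for each of 4 groups. The deposited table holds whole-number counts per gene for each library, which the authors had not normalized, per the file headers and the labels. The submitters' processing notes name HISAT2, featureCounts, DESeq2 and the mouse build mm10, with no versions or settings; the strand setting, the read pairing and the treatment of reads that match several genes are not given in the sources used here. Without a stated strand setting, reads from a gene and an antisense partner cannot be told apart. Each library was assigned to its group by its label, and each of the 8 count columns of the table matched 1 library.

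The table listed 55401 genes with Ensembl IDs, of which 23376 had 0 counts in every library, and 55141 IDs were matched to a symbol in GENCODE M21. Library totals ranged from 12119763 to 16228426 counts. Genes were kept where edgeR's filterByExpr found enough counts, which left 17125. Counts were scaled with TMM factors, and edgeR's quasi-likelihood test was fitted to all 8 libraries with 1 mean per group, so that the 4 groups shared 1 estimate of the spread (biological coefficient of variation 0.132). P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and genes were called at an adjusted p below 0.05. The contrasts were knockout against control in ESCs and in EBs, EBs against ESCs in control and in knockout, and the difference of the knockout effect between EBs and ESCs. Levels are given as CPM, computed by edgeR from the deposited counts and TMM-adjusted library sizes. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

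Samples, contrasts, gene lists, the rule for named genes and most alternatives were set before the data were examined. The rule named Zfp462 first, then per contrast the 8 genes with the highest and the 8 with the lowest log2 fold change among those called, with a mean of at least 5 CPM in the higher group and both libraries of 1 group above both of the other (a separation not asked of the difference contrast). Gene models without a gene name were passed over. It also named up to 4 members of each list with the smallest adjusted p below 0.05, and Pou5f1, Sox2, Nanog, Esrrb, Klf4, Fgf5, T and Gata6 whatever their result. Some genes that meet the rule are not reported here.

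The 26 gene lists were general pluripotency, naive pluripotency, formative and primed epiblast, primitive streak and mesendoderm, mesoderm, definitive endoderm, extraembryonic endoderm, neuroectoderm, trophectoderm, 2-cell-like, germline genes repressed by DNA methylation, fibroblast markers, proliferation, hypoxia and glycolysis, p53 targets, integrated stress response, LIF-STAT3 response, WNT targets, BMP targets, NODAL targets, FGF-ERK targets, heterochromatin factors, imprinted genes, Y-linked genes, mitochondrially encoded genes, and extracellular matrix and adhesion. Each list with at least 5 tested members was compared with the other genes by limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. The estimated correlation lay above the preset for some lists (0.262 for extraembryonic endoderm) and below it for others (-0.011 for naive pluripotency). The value with an estimated correlation is printed beside each list that was called. In knockout EBs the naive list nevertheless went from a camera adjusted p of 9.89e-09 to 0.0733. A call lost in this way therefore does not by itself show correlation between members.

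The overlap of the knockout effects was tested with Fisher's exact test. The size of the differentiation response in knockout relative to control was a slope across genes, with a jackknife over libraries for its interval. Agreement between the knockout effect and control differentiation was set beside 20 simulations of unchanged knockout libraries, since both use the same controls. The alternatives set in advance were median-of-ratios factors, library totals without composition factors, no low-count filter, a mean of at least 1 CPM, the replicate number as a block, only the libraries of the groups compared, DESeq2, a fold change of at least 2, an estimated correlation or limma's fry for the lists, and each library left out in turn. Added after the data were seen were a correction of each library's trend on GC content (a spline with 5 degrees of freedom), the split-replicate slope, and each doubtful library left out of contrasts that do not use it. Genes of adult liver and single-copy 2-cell-like genes were listed after the data were seen as well.

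The procedures were tested on simulated data drawn from the real means and library sizes, with the same spread per gene in every group. The real spread differed between groups. The SD of the log2 difference between replicates was 0.436 in control ESCs and 0.589 in knockout ESCs. The rates that follow are therefore approximate. At a planted 2-fold change 57% of genes were recovered in the ESC comparison, 60% in the EB comparison and 47% for the difference, and at 4-fold 81%, 78% and 66.5%. False calls made up 7.89%, 4.17% and 7.72% of all calls. In the ESC comparison with a simulated GC trend, 46% of 2-fold and 74% of 4-fold changes were recovered, with 5 false among 129 calls, and after correction 57% and 81%, with 12 false among 156 calls. A planted list of 15 genes changed by 1.5-fold had a camera adjusted p of 3.59e-08 with the preset correlation and 0.194 with an estimated one. The genes of that list were drawn independently of one another. Groups of 2 libraries are too small for a test of single libraries within a group.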

Results

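Gene expression was measured by RNA sequencing in R1 cells, a mouse embryonic stem cell (ESC) line, with and without a knockout of Zfp462, which encodes a zinc finger protein. Cells of each genotype were taken undifferentiated from serum medium with leukaemia inhibitory factor (LIF), a cytokine that maintains ESCs, and after 3 days as embryoid bodies (EBs), floating aggregates in which ESCs differentiate. The 4 groups, with 2 libraries each, were control ESCs, knockout ESCs, control day 3 EBs and knockout day 3 EBs. The study asked what the loss of Zfp462 does to the maintenance of stem cells and to their differentiation. The 8 libraries held from 12119763 to 16228426 gene counts. Of 55401 genes, 17125 had enough counts to be tested. Replicates were closest in control ESCs, where 20 of 11688 well-counted genes differed by more than 2-fold. There were 59 such genes in control EBs, 43 in knockout EBs and 311 in knockout ESCs. The labels do not say whether the 2 libraries of a group came from separate cultures or clones, so p-values measure only the spread between these samples, which may be technical.

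The libraries stood apart from one another in 2 further ways that bear on the groups below. Knockout ESC replicate 2 had a strong trend with GC content. Relative to the mean of all 8 libraries the 10% of genes with the lowest GC content lay higher by a median of 0.19 on the log2 scale. The 10% with the highest GC content had a median of -0.58. The difference between the 2 knockout ESC replicates had a correlation of 0.684 with GC content across genes. The corresponding values were -0.044 in control ESCs, -0.047 in control EBs and 0.022 in knockout EBs. Knockout EB replicate 1 held transcripts of adult liver. In it, all 30 of a list of adult liver genes, written after Alb, other liver genes outside the list and 1 of the 30, Cyp2c29, had been seen to be high in that library, had 10 or more counts, with a summed level of 650 CPM, a unit in which counts are scaled to library size. The other 7 libraries had 18.2 to 32.9 CPM. Alb, which encodes serum albumin, stood at 1335 CPM in knockout EB replicate 1 and at 0 in knockout EB replicate 2.

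**Figure D1:**
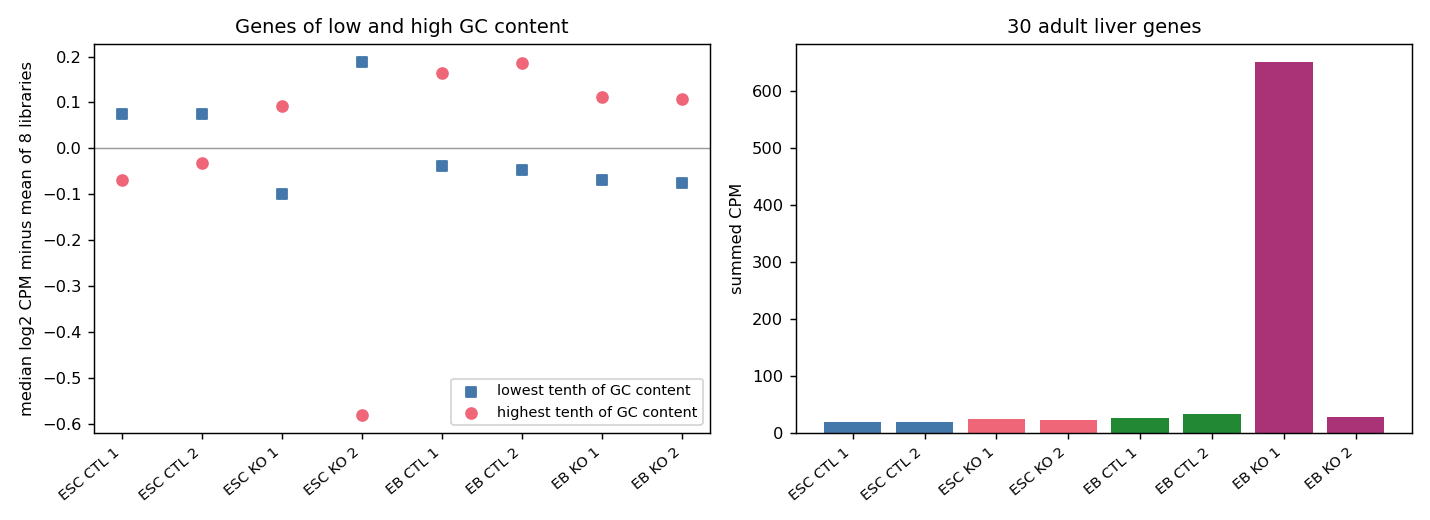
Properties of each library. Left, the median log2 CPM of the 10% of genes with the lowest (squares) and the highest (circles) GC content, relative to the mean of the 8 libraries, where knockout (KO) ESC replicate 2 lies at 0.19 and -0.58; right, the summed CPM of 30 adult liver genes per library as bars, where knockout EB replicate 1 reaches 650 and control (CTL) ESC replicate 2 has 18.2.

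Zfp462 RNA was lower in all 4 knockout libraries than in any control library, but it was far from absent. Its level was 190.1 ± 9.72 CPM in control ESCs and 105.3 ± 1.88 CPM in knockout ESCs, and 141.9 ± 16.4 CPM in control EBs and 102.2 ± 0.374 CPM in knockout EBs (mean ± SD, n = 2 each). The fall in ESCs was -0.85 ± 0.10 on the log2 scale (estimate ± SE, adjusted p = 0.000366 by edgeR's quasi-likelihood test). That left 55.4% of the control level (approximate 95% interval 48.3% to 63.5%). In EBs the fall was -0.47 ± 0.10 (adjusted p = 0.0207 by the same test), which left 72% (62.8% to 82.6%). Both intervals take a normal multiple of the SE, which is likely too narrow at 2 libraries per group. The ESC call held without any of the 4 ESC libraries, while the EB call was lost without control EB replicate 1 (adjusted p = 0.212), knockout EB replicate 1 (0.158) or knockout EB replicate 2 (0.116). The difference between the EB and ESC effects did not pass the test (0.38 ± 0.14, adjusted p = 0.304). Zfp462 (ENSMUSG00000060206.11) is a protein-coding gene on the plus strand of chromosome 4, from 54945048 to 55083563 in mm10. The edited exon is not given in the sources used here, and counts summed over a gene's exons do not show whether the transcripts that remain encode the protein, so the level of the RNA checks the labels only in part.

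**Figure D2:**
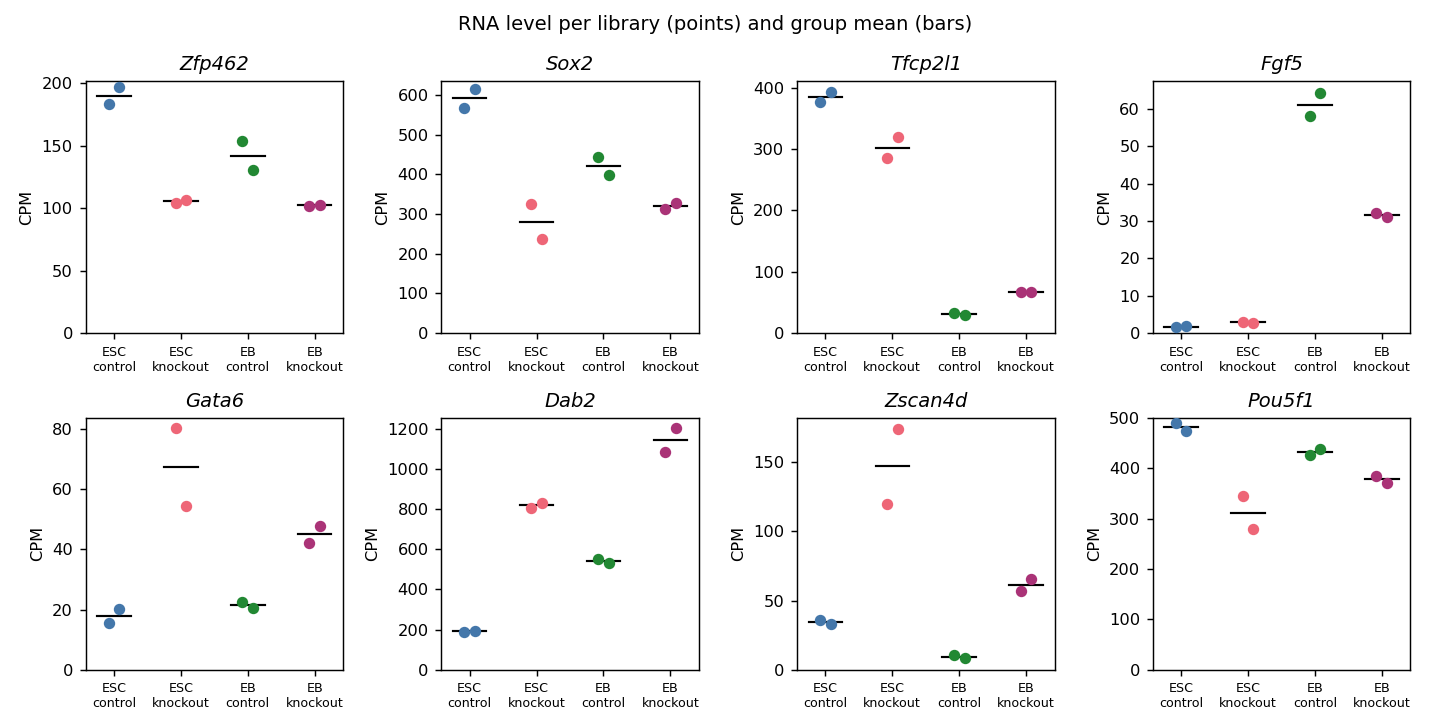
Levels of Zfp462 and of 7 marker genes in each library, in CPM on linear axes that start at 0; points are libraries and bars are the means of the 2 libraries of each group. Zfp462 lies at 190.1 CPM in control ESCs and 105.3 CPM in knockout ESCs, Sox2 at 592.4 and 281.1 CPM, Dab2 at 191.8 and 817.3 CPM, and Fgf5 at 61.16 CPM in control EBs and 31.56 CPM in knockout EBs.

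The first comparison asked what the loss of Zfp462 changed in undifferentiated ESCs. The pluripotency factors Sox2 and Pou5f1 were lower in knockout ESCs, and 20 of 23 genes of the extraembryonic endoderm, a lineage of the yolk sac, were higher. Sox2 fell from 592.4 ± 34.5 to 281.1 ± 63.0 CPM (log2 change -1.07 ± 0.13, adjusted p = 0.000466), and Pou5f1, which encodes OCT4, fell from 482.0 ± 11.7 to 312.3 ± 47.3 CPM (-0.63 ± 0.10, adjusted p = 0.00214). Nanog had a log2 difference of -0.18 ± 0.10 that did not pass the test (adjusted p = 0.286). Dab2, an endocytic adaptor of the extraembryonic endoderm, rose from 191.8 ± 2.35 to 817.3 ± 19.4 CPM (2.09 ± 0.08, adjusted p = 7.92e-07), and Gata6, which drives that lineage, rose from 17.86 ± 3.5 to 67.47 ± 18.4 CPM (1.91 ± 0.20, adjusted p = 0.000164). In mm10, Sox2 (ENSMUSG00000074637.7) lies on chromosome 3 from 34650405 to 34652461 and Pou5f1 (ENSMUSG00000024406.16) on chromosome 17 from 35506018 to 35510772. Dab2 (ENSMUSG00000022150.16) lies on chromosome 15 from 6299788 to 6440712 and Gata6 (ENSMUSG00000005836.10) on chromosome 18 from 11052064 to 11085635, and all are protein-coding genes.

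Of the 23 extraembryonic endoderm genes tested, 20 rose in knockout ESCs, 0 fell and 3 did not pass the test (21 rose when adjusted over the list alone), and the median log2 change was 1.90. The basement membrane genes Lama1 (1.90 ± 0.08) and Lamb1 (1.86 ± 0.08) were among them, each at an adjusted p of 7.92e-07. The list stood above the other genes (camera adjusted p = 6.98e-19; adjusted p = 0.326 with an estimated correlation). Its median was 1.94 with each library's trend on GC content removed and at least 1.58 without either knockout ESC library. Genes of the 2-cell-like state, the rare ESCs that express genes of the 2-cell embryo, moved the same way. Among them, 17 of 18 rose, 0 fell and 1 did not pass (17 rose when adjusted over the list alone). The median was 1.99 (adjusted p = 1.53e-15; 0.326 with an estimated correlation). Usp17la rose by 2.77 ± 0.19, Usp17le by 2.58 ± 0.19 and Usp17lc by 3.07 ± 0.22 on the log2 scale. These genes and the Zscan4, Tdpoz, Tcstv and Pramel genes belong to families of near-identical copies between which the submitters' counting could split reads, so the value of any one copy is uncertain. Of 6 single-copy genes of that state, chosen after values were seen, Zfp352, Sp110, Tmem92, Lmx1a and Arg2 rose in knockout ESCs and Dqx1 did not pass (0.26, adjusted p = 0.722). The median over the 6 was 2.23, and the first 2 are also in the list above.

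Of 15 general pluripotency genes, 6 fell in knockout ESCs, 0 rose and 9 did not pass (8 fell and 1 rose when adjusted over the list alone). The median was -0.37. Lin28a, an RNA-binding protein of early embryos, fell by 0.97 ± 0.08 on the log2 scale (adjusted p = 5.73e-05), and Trim71 fell by 0.53 ± 0.09 (adjusted p = 0.00221). The list passed the test (camera adjusted p = 0.000914; adjusted p = 0.326 with an estimated correlation). The 16 naive pluripotency genes, which mark the ground state of ESCs, split into 7 that fell, 2 that rose and 7 that did not pass. The list was not called by camera (adjusted p = 0.0814; 0.0487 without control ESC replicate 1) but was by limma's fry, which asks whether genes of a list move on balance one way (adjusted p = 0.0102). Dppa3 (-1.43 ± 0.19), Nr0b1 (-1.11 ± 0.15) and Esrrb (-0.75 ± 0.11) were among those that fell. Of the 15 genes of the formative and primed epiblast, the next stage of pluripotency, 7 fell, 3 rose and 5 did not pass. That list was not called by camera either (adjusted p = 0.0635), but was without control ESC replicate 1 (0.0446), without knockout ESC replicate 1 (0.0152) and by fry (0.0257). Zic2 (-1.60 ± 0.21), Lef1 (-1.55 ± 0.17) and Fgf15 (-1.26 ± 0.17) were among those that fell, and Car4 (1.61 ± 0.12) and Fgf5 (0.75 ± 0.22) among those that rose. The Fgf5 call was lost without control ESC replicate 1 (adjusted p = 0.228), control ESC replicate 2 (0.147) or knockout ESC replicate 1 (0.125), and by DESeq2 (0.111). Adjusted over the list alone, 7 naive genes fell and 3 rose, and 8 formative genes fell and 3 rose.

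Of 20 hypoxia and glycolysis genes, 12 fell, 2 rose and 6 did not pass, and these counts were the same when adjusted over the list alone. The oxygen sensor Egln3 (-1.29 ± 0.14), the mitophagy receptor Bnip3 (-0.83 ± 0.10) and the glycolytic enzyme Eno1 (-0.64 ± 0.07) fell, and the collagen hydroxylase P4ha1 rose (1.58 ± 0.10). That list was called (adjusted p = 0.00539; adjusted p = 0.561 with an estimated correlation). It was not called without knockout ESC replicate 2 (adjusted p = 0.0919), but it was with each library's GC trend removed. Of 9 targets of NODAL, a growth factor of the early embryo, 3 fell and 6 did not pass, with or without adjustment over the list alone. Skil fell, and Lefty1 and Lefty2 had changes of -1.22 ± 0.15 and -0.45 ± 0.08. The NODAL list had an adjusted p of 0.0354 (adjusted p = 0.326 with an estimated correlation; 0.0799 without control ESC replicate 2). Of 13 targets of the FGF-ERK pathway, 6 fell, among them Egr1 (-1.46 ± 0.25), Spry4 (-0.78 ± 0.11) and Etv5 (-0.58 ± 0.07), 2 rose and 5 did not pass (8 fell and 2 rose when adjusted over the list alone). The list passed at 0.0354 (adjusted p = 0.344 with an estimated correlation), but not without control ESC replicate 2 (adjusted p = 0.105), without knockout ESC replicate 2 (0.107) or with the GC trend removed (0.0553).

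Over all genes tested, 1421 were higher and 1062 lower in knockout ESCs at an adjusted p below 0.05 by edgeR's quasi-likelihood test, and 786 and 297 of these differed by at least 2-fold. The largest rises among genes with a mean of at least 5 CPM were in Ptk6, a tyrosine kinase (3.92 ± 0.41 on the log2 scale), and Usp17lb (3.67 ± 0.17). Next came Pramel6 (3.67 ± 0.23), Vmn1r88 (3.14 ± 0.39), Timd2 (3.12 ± 0.18) and Trim43a (3.12 ± 0.32). The largest falls were in Dtna (-3.11 ± 0.33), Mobp (-3.06 ± 0.35), Map7d3 (-2.53 ± 0.22) and Gstm3 (-2.33 ± 0.47). They were followed by Calb2 (-2.18 ± 0.28), Vrtn (-2.16 ± 0.22), the transcription factor Foxp1 (-2.09 ± 0.13) and Tfap2c (-2.02 ± 0.15), a factor of trophoblast and germ cells. The counts were 541 higher and 318 lower without control ESC replicate 1, and 485 and 271 without control ESC replicate 2. They were 1948 and 2781 without knockout ESC replicate 1, and 1734 and 1861 without knockout ESC replicate 2. With each library's GC trend removed they were 1944 and 2035, among them all 1421 higher and 1047 of the 1062 lower genes. With only the ESC libraries fitted 951 genes were higher and 407 lower.

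The second comparison asked what the loss of Zfp462 changed after 3 days of EB culture. In knockout EBs 10 of 16 naive pluripotency genes were higher than in control EBs and 9 of 15 formative and primed epiblast genes lower, and 20 of 23 extraembryonic endoderm genes and all 18 of the 2-cell-like genes were higher. Tfcp2l1, a transcription factor of naive ESCs, stood at 66.96 ± 0.972 CPM in knockout EBs and 31.51 ± 1.86 CPM in control EBs (1.09 ± 0.10 on the log2 scale, adjusted p = 0.000201). Tcl1, a coactivator of AKT signalling, stood at 29.82 ± 2.14 and 10.37 ± 0.974 CPM (1.53 ± 0.12, adjusted p = 9.83e-05). Fgf5, a growth factor that marks the formative epiblast, was lower at 31.56 ± 0.839 against 61.16 ± 4.45 CPM (-0.95 ± 0.13, adjusted p = 0.00182). Dnmt3b, a de novo DNA methyltransferase, was lower at 784.0 ± 2.58 against 1324 ± 89.6 CPM (-0.76 ± 0.08, adjusted p = 0.000506). In mm10, Tfcp2l1 (ENSMUSG00000026380.10) lies on chromosome 1 from 118627945 to 118685168 and Tcl1 (ENSMUSG00000041359.14) on chromosome 12 from 105216750 to 105222793. Fgf5 (ENSMUSG00000029337.2) lies on chromosome 5 from 98254184 to 98277030 and Dnmt3b (ENSMUSG00000027478.15) on chromosome 2 from 153649450 to 153687730.

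Of 16 naive genes, 10 were higher in knockout EBs, 0 were lower and 6 did not pass (13 were higher when adjusted over the list alone). The median was 0.71, and Tbx3 (1.35 ± 0.14), Klf4 (1.11 ± 0.15) and Fbxo15 (1.07 ± 0.12) were among them. The list was called (camera adjusted p = 9.89e-09; adjusted p = 0.0733 with an estimated correlation). Of 15 formative genes, 9 were lower, 0 were higher and 6 did not pass (13 were lower when adjusted over the list alone). The median was -0.76, and the kinase Pim2 (-1.66 ± 0.12) and the zinc finger gene Sall2 (-1.19 ± 0.12) were among them. That list was called as well (adjusted p = 1.64e-09; adjusted p = 0.113 with an estimated correlation). Of 15 general pluripotency genes 1 was higher, 1 lower and 13 did not pass (1 and 4 when adjusted over the list alone), and the list was not called (adjusted p = 0.181). Nanog was higher by 0.41 ± 0.10 (adjusted p = 0.038), a call lost without any 1 of the 4 EB libraries (adjusted p from 0.0674 to 0.231). Lin28a was lower (-0.56 ± 0.08; adjusted p = 0.0673 without control EB replicate 1). Sox2 (-0.39 ± 0.13, adjusted p = 0.11), Pou5f1 (-0.19 ± 0.10, adjusted p = 0.302) and Esrrb (0.25 ± 0.11, adjusted p = 0.225) did not pass. T, a gene of the primitive streak, had under 1 CPM in every group and did not pass (-2.63 ± 0.85, adjusted p = 0.0982).

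Of 23 extraembryonic endoderm genes, 20 were higher in knockout EBs, 0 were lower and 3 did not pass (22 were higher when adjusted over the list alone). The median was 0.93 (camera adjusted p = 4.3e-14; adjusted p = 0.143 with an estimated correlation). Cubn, an endocytic receptor (1.19 ± 0.10), Lama1 (1.16 ± 0.08), Dab2 (1.08 ± 0.08) and Gata6 (1.06 ± 0.20) were among them. The Gata6 call was lost without control EB replicate 1 (adjusted p = 0.123), control EB replicate 2 (0.117) or knockout EB replicate 2 (0.0554). In the knockout EB library with liver transcripts, Apoa1 stood at 112.2 CPM against 41.09 CPM in the other replicate and Ttr at 146.8 against 97.63 CPM, both being genes that liver also expresses. Dab2 stood there at 1085 against 1203 CPM. All 18 of the 2-cell-like genes were higher, with or without adjustment over the list alone. The median was 2.73 (adjusted p = 9.94e-22; adjusted p = 0.126 with an estimated correlation). Zscan4d was higher by 2.70 ± 0.20 and Usp17la by 3.14 ± 0.22, with the same uncertainty over copies as in ESCs. Of the 6 single-copy genes 5 were higher in knockout EBs, with a median over the 6 of 1.84, and Dqx1 did not pass (1.46, adjusted p = 0.0758). Of 8 definitive endoderm genes, 3 were higher and 5 did not pass (5 higher and 1 lower when adjusted over the list alone). The 3 were the hormone gene Trh (0.86 ± 0.09), Foxa2 (0.99 ± 0.21) and Sox17 (0.99 ± 0.23). Sox17 is also in the extraembryonic list. The endoderm list was called (adjusted p = 0.0159; adjusted p = 0.168 with an estimated correlation), but the call was lost without control EB replicate 1 (0.079), control EB replicate 2 (0.147) or knockout EB replicate 2 (0.209). The list of 16 heterochromatin factors held the histone methyltransferases G9a and GLP, HP1 proteins and other factors such as Setdb1 and Atrx. Only Cbx1, which encodes HP1 beta, was lower among those tested (-0.41 ± 0.10). The other 15 did not pass (2 were lower when adjusted over the list alone). The list was called with a median of -0.21 (adjusted p = 0.0082; adjusted p = 0.143 with an estimated correlation).

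**Figure D3:**
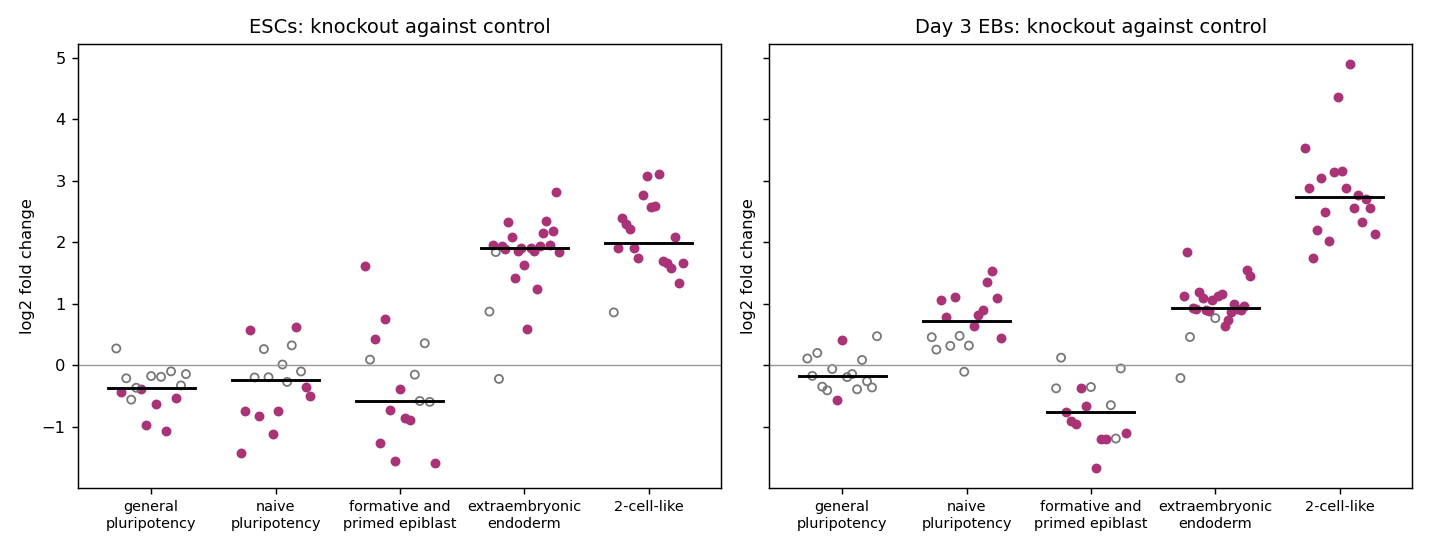
Log2 fold changes of knockout against control for the members of 5 gene lists in ESCs (left) and in day 3 EBs (right). Each point is a gene, filled where its adjusted p was below 0.05, and bars are list medians: 1.90 in ESCs and 0.93 in EBs for extraembryonic endoderm, 1.99 and 2.73 for 2-cell-like genes, -0.24 and 0.71 for naive genes, -0.58 and -0.76 for formative genes, and -0.37 and -0.17 for general pluripotency genes.

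In knockout EBs 814 genes were higher and 350 lower by edgeR's quasi-likelihood test, and 452 and 102 of these differed by at least 2-fold. The largest falls were in Jph4 (-2.50 ± 0.31), Kif1a, a motor protein of axonal transport (-2.48 ± 0.14), the non-coding RNA Miat (-2.24 ± 0.35) and Prom2 (-2.23 ± 0.40). Further falls were in Rims4 (-2.04 ± 0.38), Pla2g4a (-2.03 ± 0.27), Mapk8ip2 (-1.91 ± 0.38) and Rab25 (-1.85 ± 0.27). Of the largest rises, Cyp1a2, Fabp1, Bhmt, Akr1c14 and Serpinc1, genes of adult liver, rested on knockout EB replicate 1. Bhmt, for example, had 24.2 ± 33.1 CPM in knockout EBs. Leaving that library out was set in advance, but naming genes from that fit was chosen after its liver transcripts were seen. Without it the largest rises included Usp17lc, Usp17lb and Pramel7. Their log2 changes over all 8 libraries were 4.35 ± 0.28, 3.89 ± 0.19 and 3.73 ± 0.39. Of the 814 higher genes, 13 were over 4-fold higher in knockout EB replicate 1 than in replicate 2 and 0 the other way. The counts were 196 higher and 40 lower without control EB replicate 1, 306 and 74 without control EB replicate 2, 350 and 60 without knockout EB replicate 1, and 564 and 79 without knockout EB replicate 2. They were 1659 and 1466 without knockout ESC replicate 2, which enters through the shared spread. The share of higher genes among those called, 69.9%, was 49.8% with each library's GC trend removed (1321 higher and 1332 lower, among them 813 and 349 of the genes above). With only the EB libraries fitted 1449 were higher and 1271 lower.

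The knockout effects at the 2 stages overlapped. Of the 1421 genes higher in knockout ESCs, 540 were also higher in knockout EBs, against 67.5 for independent lists. Of the 1062 lower genes 194 were also lower, against 21.7. The odds ratio was 34.5 (95% interval 29.3 to 40.7) for the higher genes and 22.8 (18.1 to 28.6) for the lower ones. Fisher's exact test gave a p, on both sides, of 3.84e-143 for the lower genes, and for the higher genes p was too small to be represented. The intervals and this test treat genes as independent, which they are not, and the 2 stages shared 1 estimate of the spread. These values are therefore only a description. Only 7 genes were higher in ESCs and lower in EBs among those called at both stages, and 9 were the other way. Across the 17125 genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.504 and a Spearman correlation of 0.433, and the 2 comparisons shared no library. Without control EB replicate 1 the shared genes were 172 higher and 23 lower, and without knockout ESC replicate 1 they were 866 and 740. Without control ESC replicate 1 they were 253 and 56, without control ESC replicate 2 they were 236 and 51, and without control EB replicate 2 255 and 45. Without knockout EB replicate 1 they were 285 and 43, without knockout EB replicate 2 274 and 45, and without knockout ESC replicate 2 the shared lower genes were 666.

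**Figure D4:**
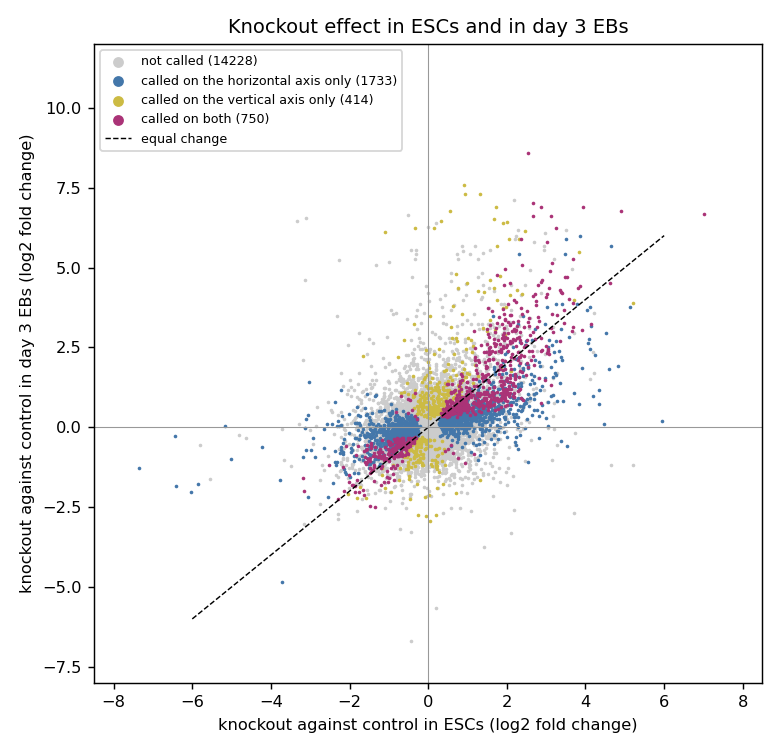
Log2 fold change of knockout against control in ESCs (horizontal axis) and in day 3 EBs (vertical axis) for each of the 17125 genes tested; colours show at which stage a gene was called and the dashed line marks equal change. Most genes called at both stages lie in the upper right (540 higher at both) or the lower left (194 lower at both).

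The third comparison tested the difference of the knockout effect between EBs and ESCs directly. Naive pluripotency genes had a median log2 effect of -0.24 in ESCs and 0.71 in EBs. Tfcp2l1 had a log2 effect of -0.35 in ESCs and 1.09 in EBs (difference 1.43 ± 0.13, adjusted p = 0.00245). Dppa3 had one of -1.43 in ESCs and 0.45 in EBs (1.89 ± 0.27, adjusted p = 0.0129). Extraembryonic endoderm genes had a median effect of 1.90 in ESCs and 0.93 in EBs, and 8 of the 23 differed by the test, a list difference not called with an estimated correlation (adjusted p = 0.465). Dab2 differed by -1.01 ± 0.11 (adjusted p = 0.00389) and Lamb1 by -1.23 ± 0.11 (adjusted p = 0.00245). These calls for single genes were lost without control ESC replicate 1, control ESC replicate 2 or control EB replicate 2, where Tfcp2l1, for example, had an adjusted p of 0.0744, 0.0821 and 0.071. Of 16 naive genes, 7 had a higher effect in EBs, 0 a lower one and 9 did not pass (all 16 passed when adjusted over the list alone). The median was 0.99 (camera adjusted p = 7.1e-14; adjusted p = 0.0265 with an estimated correlation). Of 23 extraembryonic genes, 8 had a lower effect in EBs, 0 a higher one and 15 did not pass (16 lower and 1 higher when adjusted over the list alone). The median was -0.98 (adjusted p = 6.12e-12; adjusted p = 0.465 with an estimated correlation). Of the 15 formative genes 4 had a lower effect in EBs, among them Car4 (-1.98 ± 0.16) and Dnmt3b (-1.19 ± 0.12), and 11 did not pass (6 lower and 2 higher when adjusted over the list alone). The median was -0.07 (adjusted p = 0.0421; adjusted p = 0.596 with an estimated correlation).

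Camera placed 4 further lists above the other genes for this difference, and 0 of the 4 passed with an estimated correlation. Of 18 2-cell-like genes 0 passed singly (6 were higher when adjusted over the list alone). The median was 0.68 (camera adjusted p = 0.000779; adjusted p = 0.596 with an estimated correlation; 0.138 without knockout ESC replicate 1). The 6 single-copy genes had a median effect of 2.23 in ESCs and 1.84 in EBs. Gene by gene they went both ways. The effect was larger in EBs for Zfp352 (3.10 in ESCs and 4.89 in EBs) and Tmem92 (2.15 and 2.75). It was also larger there for Lmx1a (1.85 and 1.94) and Dqx1 (0.26 and 1.46). It was smaller in EBs for Sp110 (2.39 and 1.74) and Arg2 (2.31 and 1.57). Of 15 general pluripotency genes 0 passed singly (5 were higher when adjusted over the list alone). The median was 0.27 (adjusted p = 0.00724; adjusted p = 0.593 with an estimated correlation; 0.0717 without control EB replicate 2 and 0.0787 without knockout EB replicate 2). Of 20 hypoxia and glycolysis genes 3 had a higher effect in EBs, Bnip3 (0.81 ± 0.14), Pdk1 (0.61 ± 0.13) and Hk2 (0.56 ± 0.11), and P4ha1 a lower one (-0.91 ± 0.14), while 16 did not pass. Adjusted over the list alone, 5 were higher and 1 lower (list adjusted p = 0.00724; adjusted p = 0.596 with an estimated correlation; 0.143 without knockout ESC replicate 2 and 0.136 without control EB replicate 2). Of 13 FGF-ERK targets 0 passed singly (5 were higher when adjusted over the list alone). The median was 0.41 (adjusted p = 0.0203; adjusted p = 0.593 with an estimated correlation; 0.0736 without control ESC replicate 2, 0.143 without knockout ESC replicate 2, 0.114 without control EB replicate 2 and 0.0855 without knockout EB replicate 2). The formative list of this comparison was not called without control ESC replicate 1 (0.086), knockout ESC replicate 1 (0.289), control EB replicate 1 (0.0919), control EB replicate 2 (0.0717) or knockout EB replicate 2 (0.113).

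Over all genes, the effect was higher in EBs for 127 genes and lower for 110 by edgeR's quasi-likelihood test, and 69 and 72 of these differed by at least 2-fold. Mobp (3.42 ± 0.51), Epp13 (2.46 ± 0.35), Dtna (2.39 ± 0.43) and Meiob (2.34 ± 0.46) were among the genes with the largest differences towards EBs. Stra6, the receptor for retinol-binding protein, had the largest towards ESCs (-2.99 ± 0.33, adjusted p = 0.00418), with 22.88 ± 2.71 CPM in knockout and 2.776 ± 0.104 CPM in control ESCs but 3.143 ± 0.398 and 3.03 ± 0.403 CPM in EBs. It was followed by Nrcam (-2.30 ± 0.41), Cd44 (-2.15 ± 0.40), Plat (-2.11 ± 0.27) and Pdpn (-1.99 ± 0.22). These counts changed strongly with the library left out. Such fits also have fewer libraries for the spread, which was not told apart from a dependence on single libraries. EdgeR called 0 genes without control ESC replicate 1, control ESC replicate 2 or control EB replicate 2. There 1566, 1391 and 2137 genes had an unadjusted p below 0.05, against 2136 with all 8 libraries. It called 7 higher and 15 lower without control EB replicate 1, 8 and 12 without knockout EB replicate 1 and 66 and 38 without knockout EB replicate 2. It called 1463 and 577 without knockout ESC replicate 1 and 557 and 424 without knockout ESC replicate 2. With each library's GC trend removed it called 388 and 350, among them all 127 and 110.

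The fourth comparison described differentiation itself, control EBs against control ESCs. In control cells 15 of 16 naive genes fell and 14 of 15 formative genes rose. Tfcp2l1 fell from 384.8 ± 11.1 to 31.51 ± 1.86 CPM (-3.61 ± 0.10 on the log2 scale, adjusted p = 6.1e-08). Nanog fell from 558.9 ± 22.4 to 141.4 ± 18.9 CPM (-1.98 ± 0.10, adjusted p = 2.22e-06), and Fgf5 rose from 1.695 ± 0.209 to 61.16 ± 4.45 CPM (5.15 ± 0.17, adjusted p = 1.16e-07). Pou5f1 did not pass the test (-0.16 ± 0.10, adjusted p = 0.312), and Gata6 (0.26 ± 0.20, adjusted p = 0.403) and T (-0.06 ± 0.63, adjusted p = 0.964) did not either. Sox2 fell by 0.49 ± 0.13 (adjusted p = 0.0262), a call that was lost without any 1 of the 4 control libraries (adjusted p from 0.109 to 0.218). Of 16 naive genes 15 fell and 1 did not pass (15 when adjusted over the list alone). Tcl1 (-2.81 ± 0.12) and Klf4 (-2.16 ± 0.15) were among them, and the median was -1.41 (camera adjusted p = 1.97e-13; adjusted p = 0.0295 with an estimated correlation). Of 15 formative genes 14 rose and 1 did not pass (14 when adjusted over the list alone). Pim2 (3.49 ± 0.14) and Dnmt3b (2.76 ± 0.09) were among them, and the median was 2.46 (adjusted p = 1.07e-16; adjusted p = 0.037 with an estimated correlation).

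Other groups changed in control EBs as well. Of 18 2-cell-like genes 14 fell and 4 did not pass (17 fell when adjusted over the list alone). The median was -1.99 (adjusted p = 1.27e-11; adjusted p = 0.251 with an estimated correlation). Of 23 extraembryonic endoderm genes 12 rose, among them Ttr (3.58 ± 0.25), Dab2 (1.49 ± 0.08) and Cubn (1.47 ± 0.10), 4 fell, among them Lamb1 (-0.33 ± 0.08), and 7 did not pass. The same counts held when adjusted over the list alone (list adjusted p = 0.00119; adjusted p = 0.479 with an estimated correlation). Of 12 genes of the LIF-STAT3 response 8 fell, among them Socs3 (-3.37 ± 0.27), Gbx2 (-2.60 ± 0.26) and Lifr (-1.15 ± 0.12), 1 rose and 3 did not pass. Adjusted over the list alone, 9 fell and 2 rose (list adjusted p = 0.00119; adjusted p = 0.316 with an estimated correlation). Of 11 primitive streak genes 4 rose, Wnt8a (3.72 ± 0.38), Lhx1 (3.09 ± 0.31), Fgf8 (2.32 ± 0.50) and Eomes (1.57 ± 0.16), and 7 did not pass. When adjusted over the list alone 4 rose and 1 fell (list adjusted p = 0.00305; adjusted p = 0.251 with an estimated correlation; 0.0558 with the GC trend removed). Of 9 NODAL targets 5 rose, among them Lefty1 (1.06 ± 0.14), 1 fell, Tdgf1 (-0.58 ± 0.07), and 3 did not pass. The counts were the same when adjusted over the list alone (list adjusted p = 0.0273; adjusted p = 0.251 with an estimated correlation; 0.0664 with the GC trend removed). Of 12 WNT targets 4 rose, Lef1 (2.46 ± 0.14), Axin2 (0.94 ± 0.16), Tcf7 (0.94 ± 0.17) and Ccnd1 (0.74 ± 0.10), 1 fell and 7 did not pass, with or without adjustment over the list alone. The WNT list passed at 0.0355 (adjusted p = 0.479 with an estimated correlation). It did not pass without control ESC replicate 1 (0.0618), without control EB replicate 2 (0.0829) or with the GC trend removed (0.108).

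In control EBs 1472 genes were higher and 1649 lower than in control ESCs by edgeR's quasi-likelihood test, and 585 and 719 differed by at least 2-fold. After Fgf5 the largest rises were in Afp, the fetal counterpart of albumin (4.88 ± 0.40), Fosb (4.62 ± 0.82) and the immunoproteasome subunit Psmb8 (4.22 ± 0.30). Next were Oasl2 (4.02 ± 0.28), Apoa1 (3.95 ± 0.50), Miat (3.75 ± 0.40) and Wnt8a (3.72 ± 0.38). Among the largest falls were those of Nrp2 (-3.62 ± 0.18), Tfcp2l1 (-3.61 ± 0.10), Inhbb (-3.40 ± 0.41), Socs3 (-3.37 ± 0.27) and Pla2g7 (-3.30 ± 0.27). The counts were 423 higher and 596 lower without control ESC replicate 1, 351 and 479 without control ESC replicate 2, and 557 and 646 without control EB replicate 1. They were 522 and 735 without control EB replicate 2 and 2779 and 2733 without knockout ESC replicate 2. Scaling by library totals alone moved the share of higher genes from 47.2% to 37.6%. Removal of the GC trend gave 2325 higher genes, and a fit of the control libraries alone gave 2932 higher and 2639 lower.

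The fifth comparison asked the same of knockout cells. In knockout cells 13 of 15 formative genes rose, and of 16 naive genes 10 fell and 2 rose. Fgf5 rose from 2.878 ± 0.261 to 31.56 ± 0.839 CPM (3.45 ± 0.16 on the log2 scale, adjusted p = 2.49e-06). Tfcp2l1 fell from 302.4 ± 24.9 to 66.96 ± 0.972 CPM (-2.17 ± 0.10, adjusted p = 2.49e-06) and Nanog fell from 494.3 ± 30.6 to 188.2 ± 6.44 CPM (-1.39 ± 0.10, adjusted p = 2.27e-05). Extraembryonic endoderm genes went both ways. Of 23, 9 rose, among them Ttr (3.18 ± 0.22), which lay at 146.8 CPM in the library with liver transcripts. A further 11 fell, among them Lama1 (-1.74 ± 0.08), Lamb1 (-1.56 ± 0.08) and Sox17 (-0.87 ± 0.22), and 3 did not pass. Adjusted over the list alone, 9 rose and 12 fell, and the list, with a median of -0.40 and a mean of 0.11, was not called (adjusted p = 0.389). Pou5f1 (0.28 ± 0.10, adjusted p = 0.0894), Sox2 (0.19 ± 0.13, adjusted p = 0.357), Gata6 (-0.58 ± 0.19, adjusted p = 0.0587) and T (-0.89 ± 1.01, adjusted p = 0.592) did not pass. Of 15 formative genes 13 rose and 2 did not pass (13 when adjusted over the list alone). The median was 1.67 (camera adjusted p = 2.24e-15; adjusted p = 0.0863 with an estimated correlation). Of 16 naive genes 10 fell, 2 rose and 4 did not pass (10 fell and 3 rose when adjusted over the list alone). The median was -0.65 (adjusted p = 0.000146; adjusted p = 0.125 with an estimated correlation). Of 18 2-cell-like genes 14 fell and 4 did not pass (17 fell when adjusted over the list alone). The median was -1.20 (adjusted p = 4.56e-09; adjusted p = 0.307 with an estimated correlation).

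Of 9 NODAL targets 6 rose in knockout EBs, among them Lefty1 (2.27 ± 0.15) and Eomes (1.43 ± 0.15), 1 fell and 2 did not pass. When adjusted over the list alone 7 rose and 1 fell (list adjusted p = 0.00116; adjusted p = 0.148 with an estimated correlation). Of 11 primitive streak genes 4 rose, Wnt8a by 5.96 ± 0.56 among them, and 7 did not pass. When adjusted over the list alone 5 rose (list adjusted p = 0.00332; adjusted p = 0.273 with an estimated correlation). Of 20 hypoxia and glycolysis genes 12 rose, among them Pdk1 (0.85 ± 0.09), 3 fell and 5 did not pass. With p-values adjusted over the list alone, 12 rose and 4 fell (list adjusted p = 0.00416; adjusted p = 0.42 with an estimated correlation; 0.0534 without knockout ESC replicate 2). Of 12 LIF-STAT3 genes 5 fell, among them Socs3 (-2.77 ± 0.27), 1 rose and 6 did not pass. With p-values adjusted over the list alone, 7 fell and 1 rose (list adjusted p = 0.0162; adjusted p = 0.337 with an estimated correlation; 0.141 without knockout ESC replicate 1). Of 12 WNT targets 5 rose and 7 did not pass, with or without adjustment over the list alone. Lef1 rose by 3.35 ± 0.17 and Axin2 by 1.12 ± 0.17 (list adjusted p = 0.0186; adjusted p = 0.356 with an estimated correlation; 0.137 without knockout ESC replicate 2).

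In knockout EBs 1410 genes were higher and 1217 lower than in knockout ESCs by edgeR's quasi-likelihood test, and 540 and 450 differed by at least 2-fold. Of the largest rises, Mup3, Mat1a, Apoa2, Plg and Ambp, genes of adult liver, rested on knockout EB replicate 1. Without that library the largest rises were in Wnt8a, Fosb, Oasl2, Vrtn, Psmb8, Gbp2b, Gbp2 and Afp, which over all 8 libraries had log2 changes from 3.80 ± 0.36 for Afp to 5.96 ± 0.56 for Wnt8a. The largest falls were in Myl3 (-3.93 ± 0.67), Ptk6 (-3.57 ± 0.40), Fndc1 (-3.47 ± 0.36), Timp2 (-3.33 ± 0.28), Msln (-3.23 ± 0.39), Ptger3 (-3.19 ± 0.53), Slc13a5 (-3.18 ± 0.17) and Drp2 (-3.15 ± 0.27). Of the 1410 higher genes, 34 were over 4-fold higher in knockout EB replicate 1 than in replicate 2 and 1 was the other way. The counts were 3228 higher and 2257 lower without knockout ESC replicate 1, 503 and 340 without knockout EB replicate 1 and 784 and 408 without knockout EB replicate 2. With the knockout libraries fitted alone they were 389 and 429, and scaling by library totals alone moved the share of higher genes from 53.7% to 42%.

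The genes called for differentiation in control and in knockout cells overlapped, and the size of the response in knockout relative to control was estimated. Of the genes that rose, 752 were called in both genotypes, against 121.2 for independent lists, and of those that fell 665, against 117.2. Only 14 rose in control and fell in knockout and 16 fell in control and rose in knockout. The Pearson correlation of the log2 changes across genes was 0.569. Over the 3121 genes called in control the knockout change had a slope of 0.54 on the control change (95% jackknife interval over libraries 0.394 to 0.686). With the roles exchanged, over the 2627 genes called in knockout, the slope of the control change on the knockout change was 0.619 (0.384 to 0.853). In simulated data a true slope of 1 gave 0.801 by this estimate and a true slope of 0.6 gave 0.476, so it lay below the true value there. An instrumental estimate, which selected genes on replicate 1 of the control libraries and took the slope with replicate 2, was chosen after the first slope was seen. It gave 0.738, and 0.802 with the replicates exchanged, where true slopes of 1 and 0.6 gave 0.996 and 0.617 in simulated data. In those simulations the knockout change of every gene was an exact multiple of its control change. The real changes had a correlation of 0.569, and the slope lay below 1 in either role. Differences between single genes can lower both slopes, so they do not show whether the knockout response was smaller, or by how much. The instrumental estimate was not run with the genotypes exchanged.

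**Figure D5:**
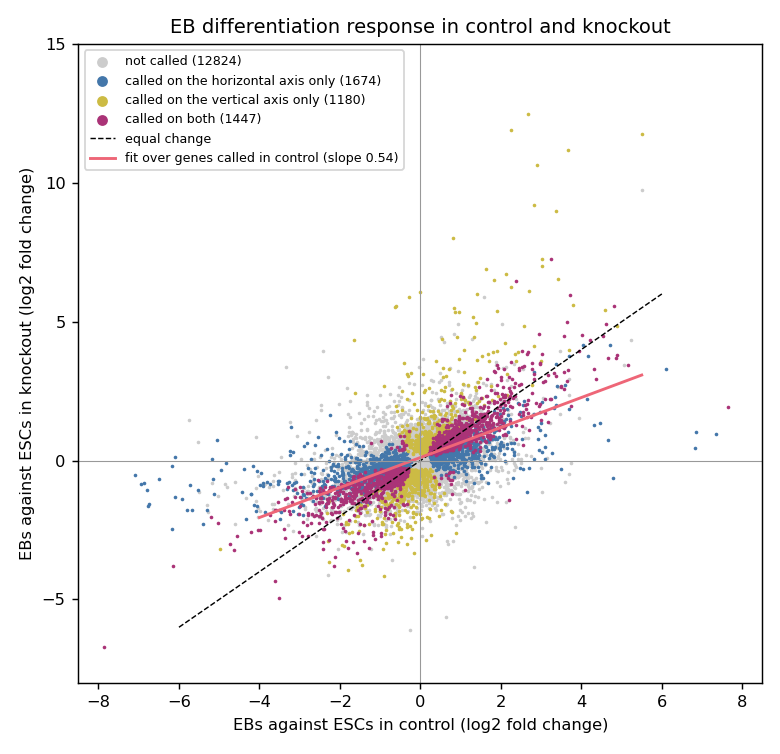
Log2 fold change of day 3 EBs against ESCs in control (horizontal axis) and in knockout (vertical axis) for each of the 17125 genes tested; colours show in which genotype a gene was called, the dashed line marks equal change and the solid line is the fit over the genes called in control, with a slope of 0.54. Points far above the dashed line near the top include the liver genes of knockout EB replicate 1.

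The last comparison asked whether the knockout effect ran along the control differentiation response. The comparisons share control libraries, so all libraries, controls included, were redrawn from the control means with the knockout unchanged. The simulation used the same spread per gene in every group. The real spread between replicates differed, with an SD of the log2 difference of 0.436 in control ESCs and 0.555 in control EBs. The simulated values are therefore approximate. In ESCs the correlation across genes of the knockout effect with the control EB-against-ESC change was 0.012 (Spearman 0.053), against 0.228 in the simulation, and 52.4% of genes had the same sign, against 57.5%. The covariance was 0.0055, against 0.0596 simulated, a difference of -0.0541 (jackknife SE 0.0418). In EBs the correlation was -0.472 (Spearman -0.43), against -0.228 simulated, and 35.2% of genes had the same sign, against 42.6%. The covariance was -0.2088, against -0.0602 simulated, a difference of -0.1486 with a jackknife SE of 0.0896. Both differences lay within 2 jackknife standard errors of 0. In the simulation the shared controls alone gave a positive correlation in ESCs and a negative one in EBs. Part of the same-direction overlaps in ESCs and of the opposite-direction overlaps in EBs, given next, may come from these controls. The other overlaps would be lowered by them. The control libraries were not divided between the contrasts here. Of the genes called in both comparisons, 336 were higher in knockout EBs and fell in control differentiation (78.4 for independent lists), 214 were lower in knockout EBs and rose (30.1), 106 were higher and rose (70.0) and 15 were lower and fell (33.7). Of those in ESCs, 263 were higher in the knockout and rose in control differentiation (122.1), 254 were lower and fell (102.3), 241 were higher and fell (136.8) and 190 were lower and rose (91.3). The covariance in ESCs was 0.1123 without control ESC replicate 1, 0.0405 without control ESC replicate 2 and -0.001 without knockout ESC replicate 1, and in EBs it was -0.403 without control EB replicate 2. No simulation was run with a library left out, so these values have no reference of their own.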

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

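Of the tests in this part, the comparisons of lineage medians and the correction for GC content were chosen after the result was seen. The results here are those where the knockout effect differed between EBs and ESCs by the test of that difference, in edgeR for genes (127 with a higher effect in EBs and 110 with a lower one) and in camera for lists; values are log2 effects in EBs minus those in ESCs, and all rest on 2 libraries per group. EdgeR called 0 genes without control ESC replicate 1, control ESC replicate 2 or control EB replicate 2, where 1566, 1391 and 2137 had an unadjusted p below 0.05.

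Among naive pluripotency genes the difference was 1.43 for Tfcp2l1, 1.63 for Tcl1, 1.89 for Dppa3, 1.07 for Nr5a2, 1.00 for Esrrb and 0.94 for Zfp42. Among formative genes it was -1.70 for Fgf5, -1.98 for Car4, -1.19 for Dnmt3b and -1.04 for Sall2. Among extraembryonic endoderm genes it was -1.01 for Dab2, -1.14 for Cubn, -0.74 for Lama1, -1.23 for Lamb1, -1.06 for Sparc and -1.22 for Srgn. Pdgfra, listed with mesoderm, differed by -1.15, and the keratin genes Krt8 and Krt18 by -0.89 and -0.76, while Tfap2c differed by 1.85. Signalling genes with a higher effect in EBs were Lefty1 (1.21), Lefty2 (0.58), the WNT inhibitor Notum (1.33) and Trh (1.33). Metabolic genes were Bnip3 (0.81), Pdk1 (0.61), Hk2 (0.56) and P4ha1 (-0.91). Matrix genes were Fn1 (1.09), Nid1 (1.01) and Cd44 (-2.15). The imprinted gene Peg3 differed by -0.81 and the histone methyltransferase gene Suv39h1 by -0.84.

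Among genes with large differences, Mobp stood at 3.42, Epp13 at 2.46, Dtna at 2.39, Meiob at 2.34, Cpsf4l at 2.11, Adgrd1 at 2.06 and Ntn1 at 1.97, and Foxp1 at 1.49. On the other side Stra6 stood at -2.99, Nrcam at -2.30, Plat at -2.11, Pdpn at -1.99, Itpripl2 at -1.90, Tspan8 at -1.88 and Timd2 at -1.79. As medians over the lists that camera called with the preset correlation, the difference was 0.27 for general pluripotency, 0.99 for naive pluripotency, -0.068 for the formative list (whose mean was -0.40), -0.98 for extraembryonic endoderm, 0.68 for 2-cell-like genes, 0.26 for hypoxia and glycolysis and 0.41 for FGF-ERK targets. With an estimated correlation the naive list passed (adjusted p = 0.0265) and the other 6 did not (adjusted p from 0.465 to 0.596), and edgeR called 0 members of the general pluripotency, 2-cell-like and FGF-ERK lists.

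The rise of extraembryonic endoderm genes in knockout ESCs was weighed against 3 explanations. A loss of stem cells to all lineages in equal measure was taken to raise the other lists alike. A fold change also depends on each gene's level in control ESCs, so the medians cannot decide this. The median of the list lay 1.48 above the highest of the neuroectoderm, mesoderm and trophectoderm medians on the log2 scale. It lay 1.25 above the definitive endoderm median (0.65), although Sox17 is in both endoderm lists. Without knockout ESC replicate 1 these gaps were smaller, at 0.74 and 0.93. A single aberrant library would remove the rise when left out, but the lower of the medians without either knockout ESC library was 1.58, and the trend with GC content would do so when corrected, but the median was then 1.94. These values argue against a single aberrant library and against the GC trend as the whole cause. They also show that the median of the extraembryonic list rose by more on the log2 scale than the medians of the other lineage lists. They cannot exclude a loss of stem cells that raises lineages unequally, and the mesoderm and definitive endoderm lists passed limma's fry (adjusted p = 0.0157 and 0.0149). An effect of the knockout and a property of the particular cell lines remain open, since the labels give no number of clones, and counts from pooled cells do not show whether some or all cells changed.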

How the results depend on the processing

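The correction for GC content, the split-replicate slope and the omission of doubtful libraries from contrasts that do not use them were chosen after the data were seen. Beyond the counts given next, 5298 values of named genes kept their direction and side of the threshold, 761 lost the call (618 of them with a library left out), 87 gained it and 1 reversed; for lists 1016 kept it, 63 lost it (32 with an estimated correlation) and 21 gained it. The reversed gene was Bax in knockout EBs against ESCs, at -0.034 with the GC trend removed (adjusted p = 0.917) against 0.47. With a change of at least 2-fold, by construction a subset, the higher and lower counts were 786 and 297 in knockout ESCs, 452 and 102 in knockout EBs, 585 and 719 for control differentiation, 540 and 450 for knockout differentiation and 69 and 72 for the difference. With only the groups compared, the spread was estimated from those libraries alone. Then 951 genes were higher and 407 lower in knockout ESCs, and 1449 and 1271 in knockout EBs. The counts were 2932 and 2639 in control differentiation and 389 and 429 in knockout differentiation. They fell in the contrasts that hold knockout ESCs, where 311 genes differed by more than 2-fold between replicates, and rose in the others. More genes were then called in knockout EBs than in knockout ESCs, the reverse of the main fit. With the GC trend removed 2035 genes were lower in knockout ESCs, 1321 were higher and 1332 lower in knockout EBs, 2325 rose in control differentiation, 388 and 350 passed for the difference, the overlap was 817 higher and 691 lower, and 5 lists were called in control differentiation. With no low-count filter the counts were 1442 and 652 in knockout EBs, 2171 higher in knockout differentiation and 448 and 256 for the difference, and DESeq2 gave 201 higher for the difference; the cause was not tested.

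Lists called were 6, 6, 8, 8 and 7 in the order above. With an estimated correlation they were 0, 0, 2, 0 and 1, and with fry, which does not compare a list with other genes, 11 in knockout ESCs, 15 in each differentiation contrast and 2 for the difference. The slope was 0.61 with a mean of at least 1 CPM and 0.738 with split replicates. The ESC covariance with differentiation was -0.0042 with a mean of at least 1 CPM, against 0.0055 in the main fit. Both lay below the 0.0596 simulated for the main fit without a knockout effect. The causes were not tested.

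With 1 library left out, the lone library of a group was assumed to vary like the others. Counts then ranged from 485 to 1948 higher and 271 to 2781 lower in knockout ESCs, 196 to 1659 and 40 to 1466 in knockout EBs, 351 to 2779 and 479 to 2733 in control differentiation, 503 to 3228 and 340 to 2257 in knockout differentiation, and 0 to 1463 and 0 to 577 for the difference, where edgeR found 1316 to 4691 genes at an unadjusted p below 0.05. Lists called ranged from 4 to 9, 5 to 6, 7 to 9, 7 to 11 and 3 to 8, the overlap from 172 to 866 higher and 23 to 740 lower, the slope from 0.468 to 0.586, the ESC covariance from -0.001 (reversed, without knockout ESC replicate 1) to 0.1123 and the EB covariance from -0.403 to -0.211.

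No large effect shared by replicate number was seen: replicate differences of 2 groups had correlations across genes from -0.089 to 0.023. The labels do not say whether samples were paired, and these correlations cannot show it. With the replicate number as a block the counts were 1294 and 987, 694 and 273, 1337 and 1503, 1279 and 1039, and 94 and 79, the overlap was 482 higher and 165 lower and the slope 0.546. The block ended 1 list call, the formative list for the difference (adjusted p = 0.0615), and 25 calls of named genes. At 12119763 to 16228426 counts per library and 2 libraries per group, simulated 2-fold changes were found for 57% of genes in ESCs, so a gene not called is not shown to be unchanged.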

Other observations

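Of the tests in this part, those on mixed cells, on liver and on delayed differentiation were chosen after the result was seen. Imprinted genes, which are expressed from 1 parental copy, went both ways. Of 19 tested, 6 rose in knockout ESCs, among them H19 (1.47), Peg3 (1.30) and Peg10 (1.03), and 5 fell, among them Nnat (-1.06), Impact (-0.73) and Snrpn (-0.67); in EBs 3 were higher, H19 (0.88), Peg10 (0.62) and Peg3 (0.49), and 4 lower, among them Phlda2 (-1.23). The list was called in neither (camera adjusted p = 0.971 and 0.777). Trophectoderm genes split in ESCs: Gata3 (2.15), Krt8 (1.25) and Krt18 (1.19) rose and Tfap2c fell by 2.02, while 6 of 10 did not pass (list adjusted p = 0.515). Of 18 genes of matrix and adhesion, Cd44 (2.27) and Itga5 (0.77) rose and 4 fell in knockout ESCs, among them Col18a1 (-1.38) and the E-cadherin gene Cdh1 (-0.64; list adjusted p = 0.814). Of 14 mesoderm genes Pdgfra (2.27), Snai1 (2.00) and Tbx20 (1.57) rose and 11 did not pass (list adjusted p = 0.0635; 0.0352 without control ESC replicate 1, and 0.0157 by fry); Pdgfra is also expressed by extraembryonic endoderm. Of 8 definitive endoderm genes 4 rose in knockout ESCs, among them Sox17 (2.15) and Cldn6 (0.84), and Trh (-0.47) and Otx2 (-0.38) fell, with the same counts when adjusted over the list alone (list adjusted p = 0.127; 0.0149 by fry).

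With all 8 libraries camera called none of the lists that follow in knockout ESCs, while limma's fry called the heterochromatin factors (adjusted p = 0.0116). Without knockout ESC replicate 1 camera called the WNT (0.0152) and germline (0.0316) lists. Of 11 primitive streak genes Wnt8a (-3.18) and Fgf17 (-1.47) fell (adjusted p = 0.481), and of 11 neuroectoderm genes Map2 (-1.41) and Pax6 (-1.07) fell, with a list median of 0.30 and a mean of -0.01 (adjusted p = 0.864). Of 16 germline genes Tex19.1 rose by 0.67 and Sohlh2 fell by 0.49 (0.308), of 15 p53 targets Plk2, Btg2 and Ccng1 rose by 0.58, 0.47 and 0.38 (0.556), and of 15 stress response genes Atf3 (1.41) and Vldlr (1.07) rose and Atf4 fell by 0.34 (0.971). Of 9 BMP targets Msx2 rose (1.29; 0.971), of 12 WNT targets Dkk1 rose (2.49) and Lef1 (-1.55) and Ccnd1 (-0.74) fell (0.0863), of 12 LIF-STAT3 genes Sgk1 (0.47) and Lifr (0.45) rose (0.558), and of 16 heterochromatin factors Suv39h1 rose (0.64) and 3 fell, among them Cbx1 (-0.47; 0.0863). Of 15 proliferation genes 1 rose and 1 fell (0.971), of 6 Y-linked genes Usp9y rose (1.99) and Uty fell by 0.55 (0.6), and of 13 mitochondrially encoded genes edgeR called 0 (0.971). Of 4 tested fibroblast markers, too few for a list test, Col1a2 rose (1.37). Median and mean log2 change in knockout ESCs also had opposite signs for imprinted genes (-0.18 and 0.09), trophectoderm (-0.04 and 0.23), stress response (-0.12 and 0.06), BMP targets (-0.07 and 0.11), Y-linked genes (-0.21 and 0.09), matrix genes (0.06 and -0.07) and proliferation genes (0.004 and -0.002), and mitochondrially encoded genes (-0.007 and -0.012) had a list test directed upward. In knockout EBs they differed in sign for WNT targets (-0.24 and 0.03), Y-linked genes (-0.13 and 0.12) and germline genes (0.02 and -0.045), and FGF-ERK targets, with a median of 0.15 and a mean of 0.10, had a list test directed downward that did not pass (camera adjusted p = 0.799). For the difference between stages they differed in sign for primitive streak genes (-0.14 and 0.11), neuroectoderm (0.17 and -0.07), imprinted genes (0.07 and -0.10) and heterochromatin factors (0.044 and -0.005). In differentiation they did so for mitochondrially encoded genes in control (-0.035 and 0.021), and in knockout, beside extraembryonic endoderm, for germline genes (-0.06 and 0.02), fibroblast markers (-0.008 and 0.10), proliferation (0.08 and -0.006) and matrix genes (-0.06 and 0.005).

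Zfp462 RNA fell but stayed well above 0 in the knockout libraries. If control cells mixed into the knockout libraries were the reason, no gene could fall below the share of control RNA that Zfp462 kept. Yet 109 genes lay below the lower bound of that share in knockout ESCs by their own approximate 95% interval. This argues against such a mixture as the whole reason. Transcripts that remain after an edit that disrupts the protein, and an edit of 1 of the 2 copies, remain open and were not tested.

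Adult liver transcripts were abundant in knockout EB replicate 1. Of the 30 listed genes, 28 had 10 or more counts there and over 5 times the CPM of the other knockout EB library, the exceptions being Cyp7b1 and Gnmt. Outside that list, Alb (1335 CPM), Mup3 (118), Cps1 (101), Apoa2 (87.5) and Cyp2e1 (87.4) were also abundant there, and control EB replicate 2 had 14.0 CPM of Alb. Hepatic differentiation within those EBs would bring Afp, but its excess was -0.2% of that of Alb (Afp 9.489 CPM against 12.1 CPM). These values are consistent with RNA from liver tissue in that library as a candidate source, while its origin is not given in the sources used here.

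A hypothesis for the higher naive and lower formative genes of knockout EBs is that knockout cells lag behind control cells along a single axis of differentiation. Of 12 extraembryonic endoderm genes that rose in control EBs, 10 were higher and 0 lower in knockout EBs by edgeR's test. Since 9 of the 10 were already higher in knockout ESCs, their level in EBs says little of the pace of differentiation. Formative genes were in part lower before differentiation too. Of 15, 7 fell and 3 rose in knockout ESCs, with a median of -0.58 against -0.76 in EBs. Naive genes had a median of -0.24 in ESCs and 0.71 in EBs. A lag stays open.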
